A study of Drosophila mojavensis with 95 samples.

How the data were processed

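RNA from whole bodies of virgin females of Drosophila mojavensis, a fruit fly of North American deserts whose larvae feed on rotting cactus, was measured on 95 one-colour NimbleGen 12-plex arrays labelled with Cy3. Per the labels, the flies came from 4 populations, 2 of them (Punta Onah and Organ Pipe National Monument) from the Sonoran side and 2 (Punta Prieta and San Quintin) from Baja California. They were reared on media made from agria or organ pipe cactus and were sampled after 0, 9 or 18 h of desiccation. Per the labels' protocols, cultures were kept at moderate larval density under a cycle of light, dark and temperature, RNA was extracted with a column kit that included a DNase step, and the array maker did the labelling. The labels name each array as a replicate of its group and do not say whether replicates came from separate cultures or extractions, so every p-value here measures only the spread between these arrays.

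The deposited table holds 1 log2 value per transcript and array, for 14528 transcripts and 95 arrays. Per the submitters' processing notes, the values were made with RMA (robust multi-array average), which corrects background, quantile-normalizes probes between arrays and summarises the probes of a transcript; no version is stated. Values ran from 4.52 to 15.6 and array medians from 10.17 to 10.40. The standard deviation over the transcripts of an array ran from 1.802 to 2.059, so the arrays did not share a single distribution of transcript values. No detection calls or background intensities were used here, and how far a dim transcript lies above background is unknown; the number of arrays limits the precision. Each of the 95 columns was matched to its sample by the sample's label, and 0 columns were left over. No 2 arrays held identical values. The median correlation over transcripts was 0.990 between arrays of 1 group and 0.980 between arrays of different groups. A note deposited with the values names 4 arrays as made from a second order of the array design. For 1 of them the note's position number and its sample do not point to the same array; the sample was used.

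Rows carry FlyBase transcript identifiers. The reference gene table given for the species lists 15130 genes, and 0 of the 14528 identifiers occur in it. Transcripts are therefore reported by identifier only, at most 2 higher and 2 lower per comparison. The 38 gene lists fixed before the data were examined could not be joined to the transcripts, so the planned gene list tests gave no result and none is reported.

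The 24 groups (population by diet by time) held 3 to 5 arrays each: 3 groups had 3, 19 had 4 and 2 had 5. The deposited log2 values were fitted with limma 3.58.1 in R 4.3.3 as 24 group means, with 71 residual degrees of freedom and no covariate, block or filter. Each comparison is a contrast of group means with equal weights. The p-values are those of limma's moderated test, two-sided, and were adjusted over the 14528 transcripts by the Benjamini-Hochberg method; a transcript was called at an adjusted p under 0.05. The tested differences were 18 h, 9 h and between them over the 8 combinations of population and diet, diet over the 12 combinations of population and time, the regions, the 2 populations inside each region, and the interactions of region with desiccation, diet with desiccation and region with diet. Changes at 18 h were also tested inside each population. Since a region stands for 2 populations, its p-values measure the spread between arrays and not the spread between populations of a region.

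Named transcripts followed a rule set before the data were examined: for the 18 h, diet, region and region by desiccation comparisons, the 2 largest rises and 2 largest falls among called transcripts, which for the first 3 had to go the same way in every stratum averaged over (8 combinations of population and diet, 12 of population and time, or both populations of a region against both of the other). This rule named none for diet. The 2 transcripts that passed the diet threshold are named because their values were seen.

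Deviations of each array from its group mean were decomposed by singular value decomposition. The first component, called the shared axis here, held 41.8% of the within-group variance and the next 6.77%. An array's score is the projection of its values on that component, centred over the arrays. Its sign was set so that it rises with the array's standard deviation. Over the arrays, the score and that standard deviation correlated at r = 0.966.

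The fit was tested on simulated data before use. Values for all 14528 transcripts were simulated with noise of the real spread, and 200 transcripts were changed at 18 h. With the real residuals drawn as whole arrays, 80.6% of the transcripts changed by 0.25 on the log2 scale were recovered, as were 100% of those changed by 0.50 and by 1.00, and 3 unchanged transcripts were called. With independent normal noise of each transcript's own spread, the shares were 82.1%, 100% and 100%, and 6 unchanged transcripts were called. In 50 data sets with no change at all, made by shuffling whole arrays' residuals, the median number called at 18 h was 0, 2 sets had any call and the highest number was 640. The highest numbers in other comparisons were 2756 for diet and 2468 for 18 h in Punta Onah, so single no-change sets can hold many false calls.

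The alternatives fixed before the data were examined were the replicate number as a block, leaving out the dimmest 25% of transcripts, a further quantile normalization, median centring, array weights, a trended and robust variance prior, fits of only the groups compared, population as a random block for the region comparisons, and leaving out each replicate number and each array. Others were chosen after seeing the data: the order of the array design as a covariate, leaving out the arrays of the second order, removing the shared axis, leaving out the 3 arrays with the lowest scores on it, leaving out the agria arrays of Organ Pipe National Monument, leaving out 2 Punta Prieta organ pipe arrays at 0 h that lay near another population, and fitting each diet alone. Where whole groups were left out, the groups that remained were weighted equally. Without its agria arrays, Organ Pipe National Monument therefore counted for less than Punta Onah in comparisons of regions. Figures were drawn with matplotlib.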

Results

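Expression of 14528 transcripts was measured in virgin female Drosophila mojavensis from 4 desert populations, reared on 2 host cacti and then held without water for 0, 9 or 18 h. The 95 arrays comprised 31 at 0 h, 31 at 9 h and 33 at 18 h. Of these, 48 were of Sonoran flies (23 from Punta Onah and 25 from Organ Pipe National Monument) and 47 of flies from Baja California (25 from Punta Prieta and 22 from San Quintin). Flies reared on agria made up 49 arrays and flies reared on organ pipe cactus 46. Values are log2 levels, and errors are standard errors (SE) of limma's fit of all 24 groups unless a standard deviation (SD) is named. No transcript could be paired with a gene name, so transcripts are given by FlyBase identifier.

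The time of desiccation left the clearest mark on the transcripts. In the median transcript, time took 14.0% of the variance between arrays, population 7.02%, diet 0.245%, and the interactions of the 3 factors 17.9%. Another 52.2% lay between arrays of the same group. These shares are not corrected for degrees of freedom, of which the interactions have far more than any single factor. Time took over 50% of the variance in 907 transcripts, population in 210 and diet in 0. The first principal component of the arrays held 40.2% of the variance; 29.1% of it lay with time and 40.9% inside groups. On the second component (11.8%), time took 56.5%, and on the third (7.35%), population took 75.1%.

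The 18 h comparison asks which transcripts differed between desiccated and undesiccated flies over all populations and diets. FBtr0166447 fell furthest, with means of 11.55 at 0 h and 10.52 at 9 h; its change at 18 h was -3.54 ± 0.0759 (SE; adjusted p = 8.65e-53 by limma), and it fell in all 8 combinations of population and diet. FBtr0167058 changed by -2.52 ± 0.203 (adjusted p = 2.72e-18). FBtr0175044 rose furthest, from 9.65 to 12.34, by 2.69 ± 0.0791 or 6.43-fold (adjusted p = 2.05e-43), and FBtr0164923 rose by 1.96 ± 0.0883 (adjusted p = 8.99e-32), both in all 8 combinations. In total 10889 of 14528 transcripts were called at 18 h, 5277 higher and 5612 lower. Most of these changes were small: the median absolute change over all transcripts was 0.195, 753 called transcripts changed at least 1.5-fold (358 higher, 395 lower) and 117 at least 2-fold (49 higher, 68 lower). With transcripts ranked by mean level into 5 equal classes, the median change was 0.17 in the second-dimmest class and -0.14 in the second-brightest. The rise in the dimmer class came mostly from Sonora, with 0.37 in Punta Onah and 0.22 in Organ Pipe National Monument against -0.0064 in Punta Prieta and 0.036 in San Quintin; the brighter class changed in the same order by -0.17, -0.19, -0.11 and -0.084. Across transcripts, the 18 h change correlated with the shared axis of within-group spread at r = -0.58 (transcripts are not independent replicates), and with that axis removed 8595 transcripts were called, 3198 higher and 5397 lower. The series holds no flies kept for 9 or 18 h without desiccation, so hours without food and the hour of the day went with desiccation time.

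**Figure D1:**
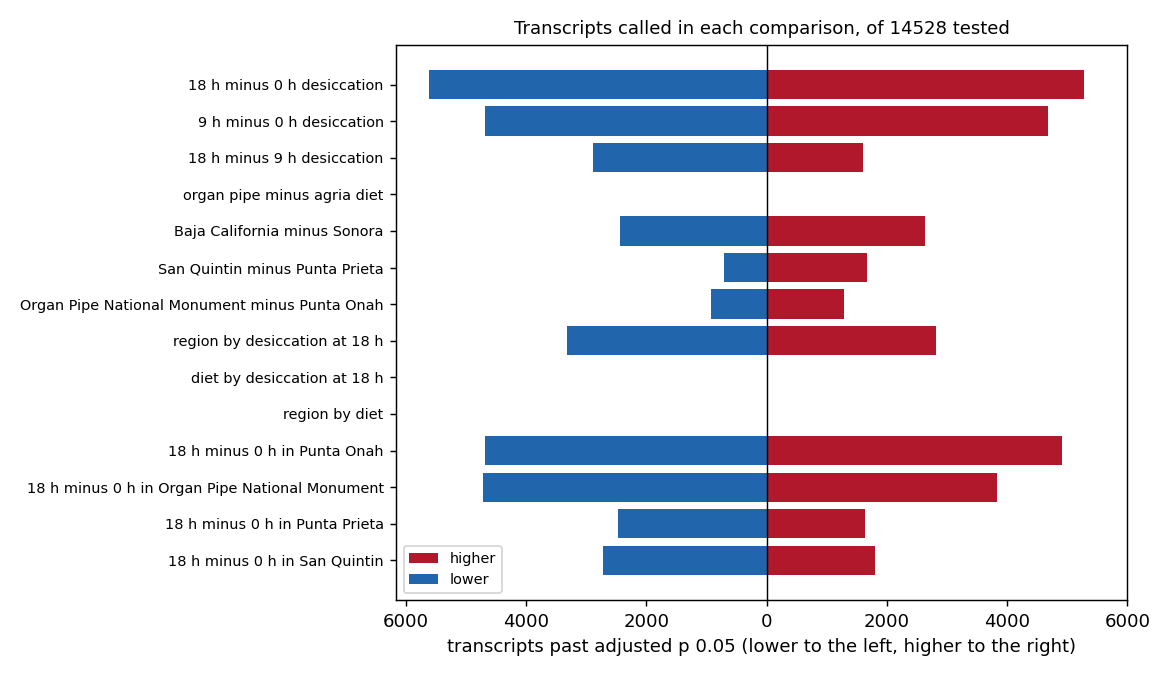
Number of transcripts past an adjusted p of 0.05 in each comparison, with those higher in the first-named condition to the right of 0 and those lower to the left. The 18 h comparison called 5277 higher and 5612 lower, and the diet comparison 2 and 0.

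The 9 h comparison asks how early transcripts moved. Many of the transcripts called at 18 h were already called in the same direction at 9 h. FBtr0175044 had risen by 1.16 ± 0.0801 at 9 h and rose by a further 1.53 from 9 to 18 h. FBtr0164923 had risen by 0.50 ± 0.0894 and then rose by 1.46. FBtr0166447 had changed by -1.03 ± 0.0768 at 9 h and changed by a further -2.51. FBtr0167058 went the other way first: it rose by 0.99 ± 0.206 at 9 h, from 11.72 to 12.71 (adjusted p = 3.86e-05), and then changed by -3.51 to 9.20 at 18 h. At 9 h 9362 transcripts were called, 4687 higher and 4675 lower, of which 204 changed at least 1.5-fold. Between 9 and 18 h 4496 were called, 1606 higher and 2890 lower. With the shared axis removed, the 9 h count was 5873.

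The 9 and 18 h comparisons use the same 0 h arrays, so an overlap of their calls is partly built in. Of the called transcripts, 4129 were higher and 4295 lower at both times, where independent lists of these sizes would share 1702 and 1806. In 50 simulated sets with no change the highest overlap was 0 in either direction, but that does not give the overlap that shared arrays add where changes are real. Opposite calls were made for 108 transcripts (higher at 9 h, lower at 18 h) and 56 (the reverse). Between 9 and 18 h, 857 of the transcripts that had risen by 9 h rose again and 357 fell, while 1738 of those that had fallen fell again and 210 rose. The changes at 9 h and 18 h correlated across transcripts at r = 0.797. With the 0 h arrays split between them, r was 0.805 or 0.762. In the simulated sets with no change, which shared all 0 h arrays, r averaged 0.536 and reached 0.917. The r of 0.797 alone therefore does not separate change from no change. The split of the 0 h arrays was not simulated. With all 0 h arrays shared, the covariance was 0.0588, against a mean of 0.00215 in the simulated sets.

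**Figure D2:**
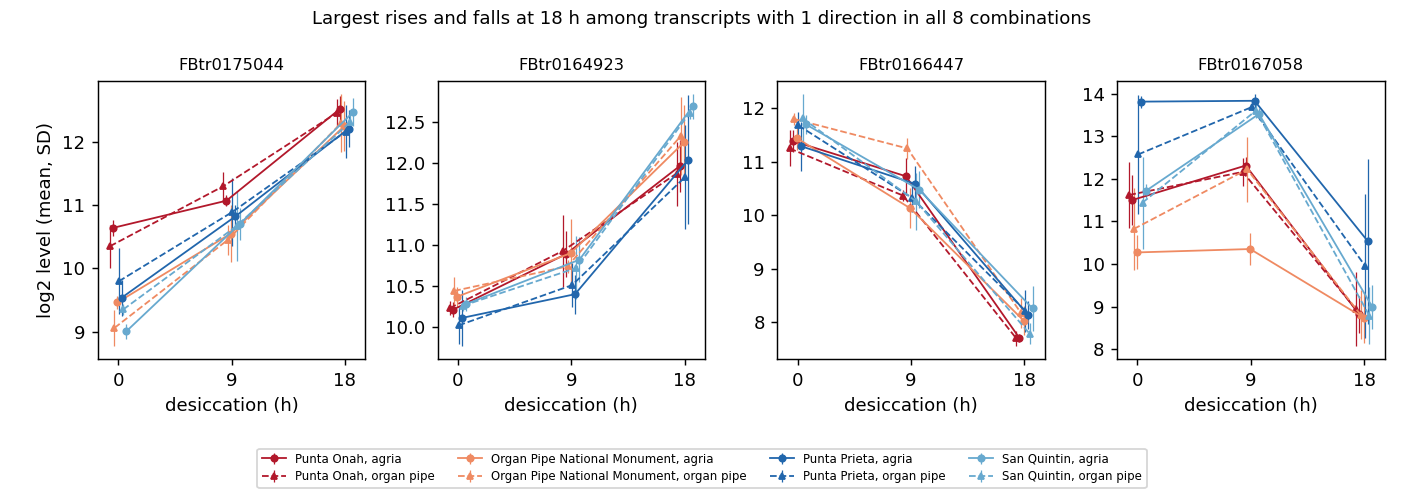
Mean log2 level (vertical axis; bars are SDs of 3 to 5 arrays) against hours of desiccation for the 2 largest rises and 2 largest falls at 18 h among transcripts that went the same way in all 8 combinations, a line per population and diet. FBtr0166447 fell in all 8 lines from 0 to 18 h, and FBtr0167058 had a mean of 12.71 at 9 h and 9.20 at 18 h.

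The diet comparison asks whether the cactus on which flies were reared altered expression, and by this measure it altered little. Only FBtr0173507 and FBtr0174959 passed the threshold, and both were chosen after their values were seen. FBtr0173507 was higher on organ pipe (11.76) than on agria (11.51), by 0.25 ± 0.0447 (adjusted p = 0.00585 by limma), and higher in 10 of the 12 combinations of population and time. FBtr0174959 was higher by 0.26 ± 0.0505 (11.12 against 10.87, adjusted p = 0.0185), in 11 of 12. Of all transcripts, 470 had an unadjusted p under 0.05, where 726 are expected with no effect, and the largest absolute difference was 0.32. The median 95% confidence interval of a transcript's diet difference reached 0.08 to either side of its estimate. Both calls ended without replicate 2, 3 or 4, although the differences of FBtr0173507 (0.25, 0.223 and 0.223) and FBtr0174959 (0.293, 0.224 and 0.214) stayed near those of all arrays. Without the first Punta Onah organ pipe array at 0 h, 4 transcripts were called.

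Averaged over the 4 populations, no effect of diet on the 18 h response was detected. The diet by desiccation interaction at 18 h called 0 transcripts in limma, with 1174 at an unadjusted p under 0.05 and a smallest adjusted p of 0.282. The region by diet interaction also called 0, with 167 at an unadjusted p under 0.05. With array weights the 3 diet comparisons called 138, 250 and 2 transcripts. The median confidence interval of the diet by desiccation interaction reached 0.20 to either side, so differences in response of that size would have been missed in many transcripts. The same interaction at 9 h, tested after the data were seen, also called 0 (smallest adjusted p = 0.176). Inside single populations it called 4 higher and 4 lower in Organ Pipe National Monument at 9 h, and in San Quintin 3 lower at 9 h and 5 lower at 18 h. With the shared axis removed these counts were 4, 4 and 14, and Punta Prieta had 2 at 9 h. The comparison in Organ Pipe National Monument uses its agria arrays at 0 h, all 4 of which lay nearest to the 9 h profile of the other flies. Diet inside this population called 35 higher and 3 lower at 9 h, and 9 and 5 at 0 h. Which arrays carry the interaction calls was not tested.

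The region comparison asks how flies from Baja California differed from Sonoran flies over diets and times. FBtr0164933 averaged 8.01 in Baja California and 5.24 in Sonora, higher by 2.77 ± 0.0853 (adjusted p = 1.36e-41 by limma). The lowest value in the table is 4.52 and a signal above background was not shown in Sonora, so this difference is a lower bound at best and no fold is given. Its population means were 7.94 in Punta Prieta, 8.08 in San Quintin, 5.29 in Punta Onah and 5.19 in Organ Pipe National Monument. The fourth Punta Prieta organ pipe array at 0 h went against its label, at 5.39 where the other 3 of its group had 7.95 to 8.25, and it lay nearest to Punta Onah over the transcripts that set the populations apart; the third array of that group lay nearest to San Quintin. Both were kept as labelled. Without them FBtr0164933 differed by 2.83 and 4771 transcripts were called between regions. FBtr0175546 was higher in Baja California by 2.35 ± 0.0851. FBtr0172679 (9.99 against 11.53) and FBtr0168456 (7.03 against 8.56) differed by -1.55 ± 0.0615 and -1.53 ± 0.0843. In total 5061 transcripts were called, 2628 higher and 2433 lower in Baja California, 184 of them at least 1.5-fold and 49 at least 2-fold. These are differences in array signal. Whether the probes bind equally well in all 4 populations was not tested. Among those 184, both Baja California means lay beyond both Sonoran means in 183, and the direction was the same at 0, 9 and 18 h in 171, as is favoured by choosing them for a large difference. Of the 184, 98 were also called for the region by desiccation interaction at 18 h, which called 42.3% of all transcripts. Calls for that interaction fell from 6143 to 1048 with the shared axis removed. How constant the regional difference was is therefore not settled. With population as a random block, 1614 transcripts were called. That fit used a single correlation within populations for all transcripts (0.0635). It does not measure each transcript's own spread between populations of a region.

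**Figure D3:**
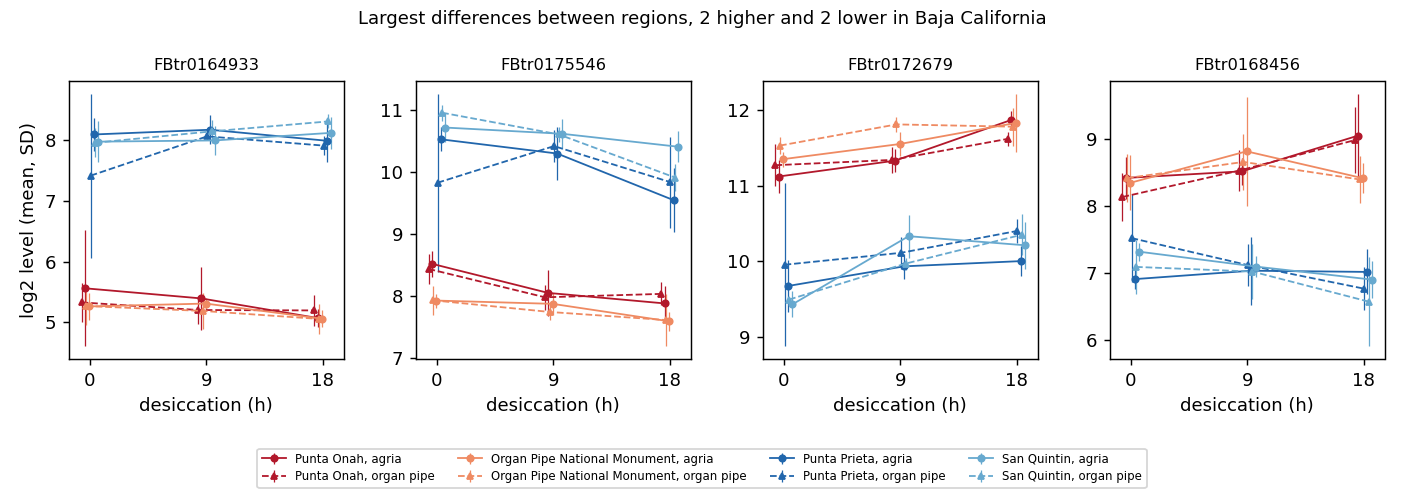
Mean log2 level (vertical axis; bars are SDs of 3 to 5 arrays) against hours of desiccation for the 2 transcripts furthest above and the 2 furthest below Sonoran levels in Baja California, a line per population and diet, with Sonoran populations in reds and Baja California populations in blues. FBtr0164933 averaged 8.01 in Baja California and 5.24 in Sonora.

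Populations inside a region also differed. San Quintin and Punta Prieta differed in 2369 transcripts (1667 higher and 702 lower in San Quintin), 49 of them at least 1.5-fold. Organ Pipe National Monument and Punta Onah differed in 2217 (1294 higher and 923 lower in the former), 120 of them at least 1.5-fold. The count of this Sonoran pair was 4471 with array weights and 1278 without replicate 1 (649 higher, 629 lower). It also fell by over 1.5 times on agria alone. The San Quintin comparison correlated across transcripts with the shared axis at r = 0.702. Its split turned with the scaling, from 70.4% higher as deposited to 34.5% with each array centred on its median, and leaving out the fourth Punta Prieta agria array at 9 h raised its count to 3569. Without the 2 Punta Prieta arrays near another population the count was 3149, and with array weights 6842. It fell to 1091, 1290 and 1098 without replicates 1, 2 and 3, to 1551 with the axis removed, and to 988 and 646 on organ pipe and agria alone. Transcripts that stood at least 1.5-fold apart from all 3 other populations, while those 3 lay within 1.5-fold of each other, were most frequent in Punta Onah, with 25 higher and 3 lower. They numbered 7 and 8 in Organ Pipe National Monument, 6 and 0 in Punta Prieta and 3 and 4 in San Quintin; no test was run on these counts.

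Each population's own 18 h response was described next. Calls numbered 9586 in Punta Onah (4907 higher, 4679 lower), 8551 in Organ Pipe National Monument (3834, 4717), 4111 in Punta Prieta (1641, 2470) and 4519 in San Quintin (1803, 2716). The Punta Prieta split turned to 2013 higher and 1796 lower with median centring, and its count was 2376 from its own arrays alone, 1975 without replicate 3 and 2915 without its 2 arrays near another population. San Quintin had 7378 with array weights, and 2930 and 2716 without replicates 1 and 3. Organ Pipe National Monument had 5646 without its agria arrays. On agria alone the 4 populations had 5141, 5109, 2127 and 2136, and on organ pipe alone Punta Prieta had 1423. In all 4 populations 811 transcripts were called higher and 1214 lower, 12099 were called in at least 1, and 203 were called higher in some and lower in others. FBtr0166447 changed by -3.62, -3.52, -3.31 and -3.73 in Punta Onah, Organ Pipe National Monument, Punta Prieta and San Quintin. FBtr0175044 rose by 1.99, 3.02, 2.52 and 3.21 in the same order. Responses of different populations, which share no arrays, correlated across transcripts at r = 0.553 (Punta Onah and Punta Prieta) to 0.839 (the Sonoran pair). With the shared axis removed this order did not hold: the Sonoran pair had 0.693, the Baja California pair was highest at 0.804, and Punta Onah and Punta Prieta had 0.764. Where both populations of a pair called a transcript, 97.5% to 99.6% of calls had the same direction. The root mean square change was 0.463 in Punta Onah, 0.385 in Organ Pipe National Monument, 0.278 in Punta Prieta and 0.318 in San Quintin, and with the shared axis removed it was 0.278, 0.291, 0.276 and 0.309, with 4888, 6455, 5176 and 5380 transcripts called.

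The region by desiccation interaction asks whether the 18 h response differed between regions. FBtr0165571 rose by 2.08 in Baja California (8.76 to 10.84) and by 0.87 in Sonora (9.12 to 9.98), a difference of 1.21 ± 0.253 (adjusted p = 0.000752 by limma). FBtr0171495 changed by -1.72 in Baja California and -2.88 in Sonora, a difference of 1.15 ± 0.29 (adjusted p = 0.00285 by limma). Punta Onah stood furthest apart in this transcript, at -3.51. Organ Pipe National Monument had -2.24, Punta Prieta -1.92 and San Quintin -1.53. In San Quintin its means were lower at 9 h (9.75 on agria, 9.99 on organ pipe) than at 18 h (10.76 and 10.24). The other combinations were lower at 18 h than at 9 h. FBtr0165571 and FBtr0171495 lost their calls in fits of a single diet, which hold fewer arrays. FBtr0165571 did so on organ pipe (0.987, adjusted p = 0.082 by limma). FBtr0171495 did so on organ pipe (1.33, adjusted p = 0.059) and agria (0.977, adjusted p = 0.0733). The largest negative differences, -2.03 ± 0.435 for FBtr0174470 and -1.86 ± 0.383 for FBtr0166499, rested on a single population. FBtr0174470 rose by 1.11 in Organ Pipe National Monument and changed by -3.86, -3.47 and -3.34 in Punta Onah, Punta Prieta and San Quintin, and FBtr0166499 rose by 1.67 against -2.38, -2.32 and -2.10. Without the agria arrays of Organ Pipe National Monument these differences were -0.67 and -0.60, with adjusted p of 0.245 and 0.236 by limma. That fit weighted the remaining Sonoran groups equally, so Organ Pipe National Monument counted for less than Punta Onah. The size of the drop therefore does not measure the part of the agria flies alone. In the organ pipe flies of Organ Pipe National Monument, FBtr0174470 went from 11.31 at 0 h to 10.81 at 18 h, and FBtr0166499 from 13.54 to 13.47.

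In total 6143 transcripts were called for this interaction, 2820 with a higher and 3323 with a lower change in Baja California, and 799 of them differed at least 1.5-fold. Across transcripts the interaction correlated with the shared axis at r = 0.847. The mean array SD changed from 1.987 ± 0.0379 (SD, n = 15) at 0 h to 1.903 ± 0.0536 (SD, n = 17) at 18 h in Sonora, and from 1.959 ± 0.0524 (SD, n = 16) to 1.953 ± 0.0472 (SD, n = 16) in Baja California. The mean score on the axis went from 18.2 ± 15.4 (SD) to -18.6 ± 23.8 in Sonora and from 9.49 ± 22.7 to 1.65 ± 17.0 in Baja California. With the axis removed 1048 transcripts were called, 343 higher and 705 lower, of which 785 were also among the 6143. Other settings also moved the count by over 1.5 times: to 575 on organ pipe alone, 1352 on agria alone, 2038, 2018 and 3512 without replicates 1, 2 and 4, and 4052 without the 3 arrays of lowest score. The number of transcripts is therefore not steady. The difference between regions itself correlated across transcripts at r = 0.643 between 0 and 9 h, 0.624 between 9 and 18 h and 0.106 between 0 and 18 h, and at r = 0.906 between the diets.

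**Figure D4:**
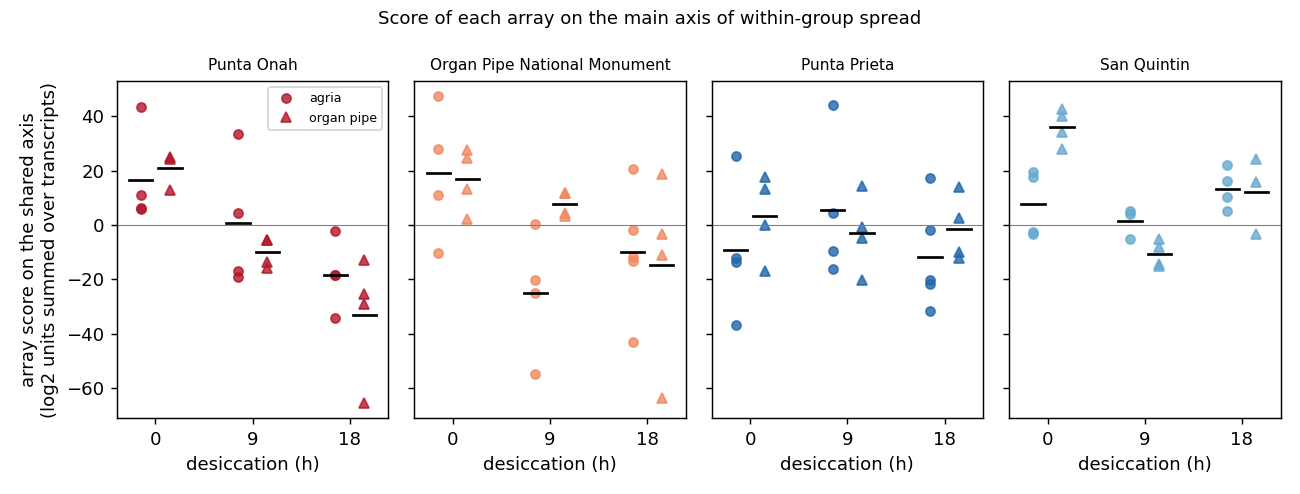
Score of each array on the shared axis of within-group spread (vertical axis, log2 units summed over transcripts) by hours of desiccation, a panel per population, with circles for agria, triangles for organ pipe and bars for group means. Sonoran arrays averaged 18.2 at 0 h and -18.6 at 18 h, and Baja California arrays 9.49 and 1.65.

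**Figure D5:**
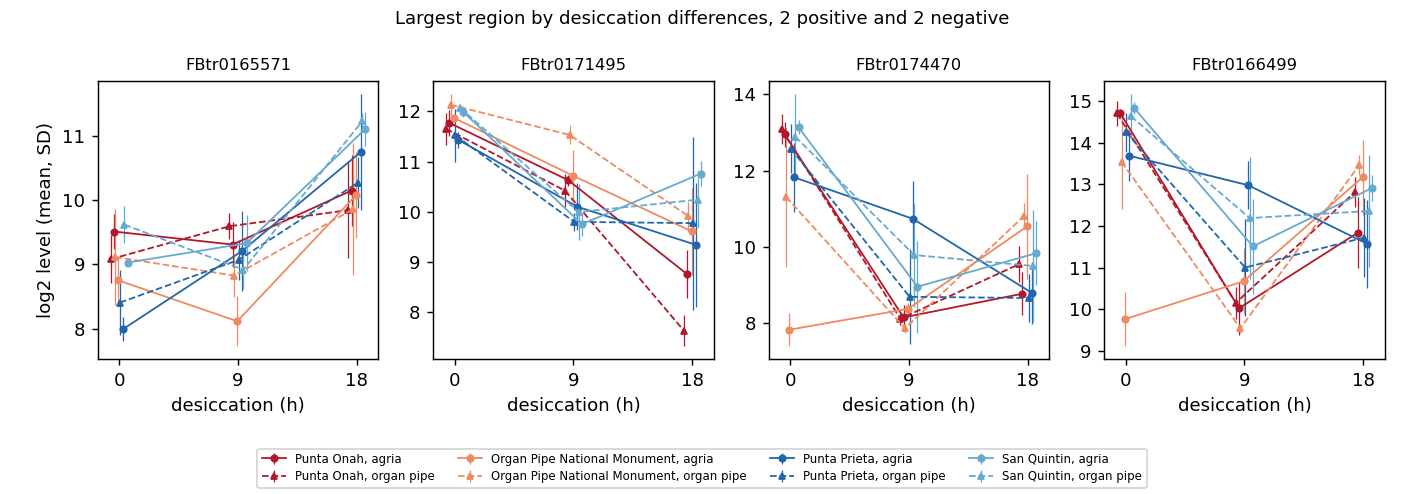
Mean log2 level (vertical axis; bars are SDs of 3 to 5 arrays) against hours of desiccation for the 2 largest positive and 2 largest negative region by desiccation differences, a line per population and diet. FBtr0174470 averaged 7.83 in the agria flies of Organ Pipe National Monument at 0 h, while the other 0 h groups averaged 11.31 to 13.14.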

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

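The tests that remove the shared axis, the reading of the quantile normalization, those on the agria flies of Organ Pipe National Monument at 0 h and the one on flies kept without desiccation were chosen after the results were seen; the regroupings of labels and the tests on axis scores were set before their outcomes were known.

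The fourth Punta Onah agria array at 0 h stood apart from the others of its group, with an array SD of 2.059 against 1.964 to 1.970 and an axis score of 43.4 against 6.03 to 10.9. It is 1 of the 4 arrays of that group and was not among the 4 arrays of the second order. These were the only flags in 42 group tests of array SD and score, where chance gives about 2.1.

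The response to 18 h of desiccation differed between regions by the interaction test in 6143 transcripts. Among named transcripts, the Baja California change less the Sonoran change was 1.21 in FBtr0165571, 1.15 in FBtr0171495, -2.03 in FBtr0174470 and -1.86 in FBtr0166499. FBtr0168456, named for its lower level in Baja California, differed by -0.78 ± 0.206 (SE, adjusted p = 0.00391 by limma). It changed by 0.39 in Sonora and by -0.40 in Baja California. The Sonoran rise was that of Punta Onah (0.745), with 0.0245 in Organ Pipe National Monument. Punta Prieta changed by -0.326 and San Quintin by -0.469.

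The first pattern weighed is the region by desiccation interaction, which lies mostly along the axis on which arrays of 1 group differ. Arrays scattered along the axis without regard to group are argued against: the score changed by -37.4 in Sonora and -6.35 in Baja California, a difference of 31.1 (groups weighted equally, where the means per region weight arrays equally) with a two-sided permutation p of 0.0033 (100000 shuffles of population labels within diet and time). Unequal value distributions are argued against too, though only as the whole cause: after a further quantile normalization 4953 transcripts were called, 4300 of them among the 6143 and all 4300 in the same direction, while the split turned from 2820 higher and 3323 lower to 2700 and 2253. The axis is not the whole cause either, since 1048 were called without it, 785 of them among the 6143 and 783 in the same direction. For the transcripts lost with the axis, a technical shift that went along with the groups cannot be told apart from a larger Sonoran response: the score did not follow the replicate number (permutation p = 0.86), and the labels give no hybridisation batch to test. The biological explanation, a response of different size in the 2 regions, stays open and untested beyond this.

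The second pattern is the breadth of the 18 h response, with 10889 of 14528 transcripts called. The shared axis is argued against as its whole cause, since 8595 were called without it. That test covers only this single direction of spread between arrays. Of the 8595, 7334 were also among the 10889, and 6997 of these had the same direction. The 10889 are 75% of all transcripts, so a large overlap would arise by chance and is not counted as evidence. Hours without food or the hour of the day cannot be told apart from dry air, because the series holds 0 arrays of flies kept as long without desiccation. A response to drying is therefore only 1 of the open explanations.

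The third pattern is the agria flies of Organ Pipe National Monument at 0 h, which stood near 9 h levels in the transcripts that changed most by 9 h. Over the 50 transcripts with the largest 9 h change in the other 7 combinations of population and diet, the median ratio of this combination's change to theirs was -0.031, while that of 6 of the others was 0.87 or more, and on 200 time-dependent transcripts all 4 of these 0 h arrays lay nearest to the 9 h profile of the other combinations. An exchange of labels with the 9 h arrays of the same flies is argued against, since 0 of those 4 arrays lay nearest to the 0 h profile. Arrays of 9 h flies under a 0 h label stay open. Over all transcripts, with the shared axis removed, the change from 0 to 9 h correlated with that of the other combinations at r = 0.491. The highest of 99 chance sets of arrays had 0.364, and with the axis left in, r was 0.669. How far separately collected groups of 9 h flies would correlate by this measure was not tested, so r does not decide. Of the 50 transcripts, 21 changed in the same direction as in the other combinations. Another hour of collection or feeding state at 0 h stays open too. It cannot be told apart from a trait of these flies on this diet, since 0 arrays carry an hour of collection in their labels. Of the 4 organ pipe arrays of this population at 0 h, 1 also lay nearest to the 9 h profile. The state was therefore not shown to be confined to agria.

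Regrouping the arrays tested whether chance could give as many calls; each comparison had 100 groupings, the real one included. For 18 h, 9 h and 18 h against 9 h, time labels were shuffled within population and diet, and only the real grouping (1 of 100) reached 10889, 9362 and 4496 transcripts; the highest of the others were 1, 0 and 2797. Inside Punta Onah, Organ Pipe National Monument, Punta Prieta and San Quintin it was again 1 of 100, with 9586, 8551, 4111 and 4519 against 918, 4249, 903 and 2. With population labels shuffled, 1 of 100 again reached the real counts. These were 5061 against 14 for the regions, 2369 against 18 for the Baja California pair and 2217 against 16 for the Sonoran pair. The region by desiccation interaction had 6143 against 35, and without the axis 1048 against 165. A chance assignment of arrays to labels is argued against for all of these, at this number of groupings. For the regions and their interaction, the shuffles mixed arrays of all 4 populations. They cannot tell whether 2 populations would differ from 2 others by chance. For diet, 4 of 100 groupings called at least the real 2 transcripts, the real one included, a share too near 0.05 to settle whether 2 calls arose by chance, and the highest called 3238; for diet by desiccation and region by diet, all 100 called at least the real 0, with highest counts of 2825 and 23. Groupings that call so many more than the real one point to a structure of the samples. With the shared axis found anew and removed, the 2 diet groupings with 3238 and 2825 calls called 0 and 0, and the highest of the others called 59 and 3, so those calls lay along the axis.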

How the results depend on the processing

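Over all alternatives, 266 counts lay within 1.5 times of the reported ones and 47 did not. For named transcripts, 300 values kept direction and side of the threshold, 16 lost the call, and none turned. Axis, lowest scores, array order, agria or Punta Prieta arrays left out and single diets are alternatives chosen after seeing the data. Signal over background is unknown. The planned gene list tests were not run, as no transcript was joined to a gene.

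Same-numbered arrays did not deviate together: the mean correlation of deviations was -0.0096 for the same number and 0.0034 for different numbers, and 11 of 95 arrays correlated best with their own number. With the replicate number as a block, 10934 transcripts were called at 18 h, 6065 for the region by desiccation interaction, 5016 between regions and 3 for diet, and no count in any comparison moved by over 1.5 times.

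Array weights called 138 transcripts for diet, 250 for diet by desiccation, 2 for region by diet, 6842 for San Quintin against Punta Prieta, 4471 for Organ Pipe National Monument against Punta Onah and 7378 in San Quintin at 18 h; the cause was not tested. Fitting only its own arrays gave 2376 in Punta Prieta, but 5876 in San Quintin against 4519 in the full fit. Fewer arrays estimate the spread in both, so that alone does not account for the drop in Punta Prieta. Its cause was not tested. Population as a random block gave 1614 between regions. With the axis removed, the counts were 5873 at 9 h, 1551 for San Quintin against Punta Prieta, 1048 for region by desiccation and 4888 in Punta Onah. Without the 3 arrays of lowest score, they were 4052 for region by desiccation and 1 for diet; without the second-order arrays, with or without the array at the stated position, diet gave 1. Without its agria arrays, Organ Pipe National Monument gave 5646.

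Fits of a single diet hold fewer arrays. On organ pipe alone, the counts were 1996 (18 h against 9 h), 2825 (regions), 988 (San Quintin against Punta Prieta), 575 (region by desiccation) and 1423 (Punta Prieta at 18 h). On agria alone, they were 3782 (9 h), 2604 (regions), 646 (San Quintin against Punta Prieta), 706 (Organ Pipe National Monument against Punta Onah), 1352 (region by desiccation), and at 18 h 5141 in Punta Onah, 5109 in Organ Pipe National Monument, 2127 in Punta Prieta and 2136 in San Quintin.

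Leaving out replicate numbers or arrays gave 0 to 4 transcripts for diet, 0 to 6 for diet by desiccation, 2018 to 7078 for region by desiccation, 1091 to 3569 for San Quintin against Punta Prieta, 1278 to 2386 for Organ Pipe National Monument against Punta Onah, 1975 to 4791 in Punta Prieta and 2716 to 4770 in San Quintin. Single arrays moved a count by over 1.5 times only for diet and San Quintin against Punta Prieta (3569 without the fourth Punta Prieta agria array at 9 h).

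Under quantile normalization, median centring or axis removal, the split of calls moved by over 10 points in 5 cases. San Quintin against Punta Prieta went from 70.4% higher to 56.5% after quantile normalization and 34.5% with median centring; Punta Prieta at 18 h went from 39.9% to 52.8% with median centring. With the axis removed, the 18 h comparison went from 48.5% to 37.2% and region by desiccation from 45.9% to 32.7%. Other settings moved it too: region by desiccation to 57.3% without the dimmest 25%, and San Quintin against Punta Prieta to 54.4% with array weights and 88.9% without replicate 1, among others. None of the scalings moved the median of all transcripts by over 0.1. The named calls that ended for diet were FBtr0173507 and FBtr0174959 (adjusted p up to 1 without replicate 3). In region by desiccation, FBtr0174470 and FBtr0166499 lost theirs without the agria arrays of Organ Pipe National Monument (-0.67 and -0.602, from -2.03 and -1.86). That fit also gave this population less weight than Punta Onah. Both transcripts lost their calls on organ pipe alone too (-1.63 and -1.42, adjusted p = 0.108 and 0.102 by limma). So did FBtr0171495 on either diet (1.33 and 0.977) and FBtr0165571 on organ pipe (0.987).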

Other observations

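The tests in this part were chosen after the data were seen.

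The agria flies of Organ Pipe National Monument and of Punta Prieta differed from the other combinations in their early time course. For the Punta Prieta agria flies, the 9 h change of the 50 transcripts with the largest change elsewhere had a median ratio of 0.22 to that of the other 7 combinations, against 1.1 on organ pipe; at 18 h the ratios were 0.90 and 0.99. On 200 time-dependent transcripts, with the shared axis removed, 2 of the 4 Punta Prieta agria arrays at 0 h lay nearest to the 9 h profile of the other combinations, as did 2 of the 5 at 18 h. Over the whole series 86 of the 95 arrays lay nearest to the profile of their own time. The other 9 were these 4, the 4 agria arrays of Organ Pipe National Monument at 0 h and 1 of the 4 organ pipe arrays of that population at 0 h.

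FBtr0174470, which had the largest fall of all transcripts at 9 h (-3.11 ± 0.22, SE), is an example. Its level was 7.83 ± 0.435 (SD, n = 4) in the agria flies of Organ Pipe National Monument at 0 h, while the other 27 arrays at 0 h had a median of 12.8 and ran from 8.68 to 13.6. In Punta Onah it went from 12.95 ± 0.318 to 8.16 ± 0.333 by 9 h on agria and from 13.09 to 8.12 on organ pipe. In the Punta Prieta agria flies it was 11.83 ± 0.901 at 0 h and 10.74 ± 0.995 at 9 h. Its mean over all flies was 8.84 at 9 h and 9.56 at 18 h. FBtr0166499 had the same shape, at 9.76 ± 0.653 in the agria flies of Organ Pipe National Monument at 0 h against a median of 14.6 (11.9 to 15.1) in the other 27 arrays.

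Replicates 3 and 4 of the Punta Prieta organ pipe arrays at 0 h did not resemble the others of their group. Each array was set against the mean of each population at its own time, over the 200 transcripts with the largest range between populations, chosen without that array and with the shared axis removed. Replicate 4 lay at a root mean square distance of 0.446 from Punta Onah and 1.48 from Punta Prieta, and replicate 3 at 0.356 from San Quintin and 1.00 from Punta Prieta. In all, 87 of 95 arrays lay nearest to their own population; of the other 8, only these 2 were over 1.5 times as far from their own as from the nearest. No Punta Onah array lay nearest to another population, so replicate 4 has no partner of an exchange there. A wrong label in 1 direction needs no partner and was not tested. The Punta Onah organ pipe group at 0 h is 1 of the 3 groups with only 3 arrays. The arrays stayed under their labels, and leaving both out moved no count by over 1.5 times: region by desiccation had 6804, and Punta Prieta at 18 h had 2915 (1418 higher, 1497 lower).

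Diet differences inside single combinations of population and time were few but not evenly spread. San Quintin at 0 h had 40 transcripts higher on organ pipe and 0 lower, Organ Pipe National Monument at 9 h had 35 higher and 3 lower and at 0 h 9 higher and 5 lower, and Punta Prieta at 0 h had 2 higher and 7 lower. The other 8 combinations had 3 or fewer. All 4 agria arrays of Organ Pipe National Monument at 0 h lay nearest to the 9 h profile of the other flies. Of the Punta Prieta organ pipe arrays at 0 h, 2 lay nearest to another population. Whether these arrays carry the diet calls at 0 h was not tested. Unadjusted p-values under 0.05 numbered 4217 in Organ Pipe National Monument at 9 h and 2794 in San Quintin at 0 h, against 114 in Punta Onah at 9 h, with 726 expected. Mean axis scores on agria and organ pipe were -25.0 ± 22.8 and 7.76 ± 4.61 (SD, n = 4 each) in the first of these and 7.76 ± 12.5 and 36.1 ± 6.48 (SD, n = 4 each) in the second.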
